A study of Mus musculus with 4 samples.

How the data were processed

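RNA from microdissected mouse cranial neural tubes at embryonic day 10.5 was sequenced in 4 libraries, each from a separate embryo. 2 libraries, Control 1 and Control 2, came from embryos without the Cre transgene, and 2, DCKO 1 and DCKO 2, from embryos with both floxed Lats1 and both floxed Lats2 alleles and the E2f1 Tg(Wnt1-cre)2Sor transgene. Whether the Control embryos carried floxed alleles, and the sex of the embryos, are not stated. The labels describe polyadenylated RNA, a stranded library kit and an Illumina sequencer, but the counts include much ribosomal RNA cluster and other RNA without poly(A) tails, so whether poly(A) selection was used is uncertain.

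The authors deposited a table of read counts per Ensembl gene, with 1 column per library and no scaling. They also deposited TPM, the length-scaled abundance of transcripts, per gene and a table of differential expression with a log2 fold change, a p-value and a false discovery rate. The submitters' processing notes name TopHat2 2.1.1, StringTie without a version, edgeR 3.16.5, limma 3.30.13, R 3.3.2 and the mouse builds mm10 and GRCm38, without roles or order. How the whole numbers of the count table were made, and whether strand was used in counting, are not stated. Values of genes that overlap another gene or have near-identical copies are therefore uncertain in their assignment. In the differential expression table, the sign was checked against the counts: positive values are higher in DCKO.

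Of the 54532 gene IDs in the count table, 54409 matched the reference table of symbols and 123 did not. Coordinates are those of GENCODE mouse release M21 on GRCm38. Library totals were 55137810 and 45190611 counts in Control and 45102704 and 41798361 in DCKO. In these totals, a floor of 3 counts in 1 library corresponds to between 0.0479 and 0.0812 CPM, the usual depth-scaled unit of counts, with TMM-scaled totals as the depth. Such floors, and the 95% intervals given for ratios of few counts, cover counting error alone, since the reads carry no molecular identifiers.

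Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 19207 genes. Libraries were scaled by trimmed mean of M values (TMM), with factors of 1.14, 1.12, 0.888 and 0.885 for Control 1, Control 2, DCKO 1 and DCKO 2. A quasi-likelihood model with group as its only term was fitted, which leaves 2 residual degrees of freedom. Benjamini-Hochberg adjusted p-values were computed over all tested genes, with a threshold of 0.05. All tests were two-sided. Standard errors (SE) of log2 fold changes were derived from the fold change and the F statistic. CPM are given as mean ± SD with n = 2 per group. Where all libraries of a group held 0 counts, the fold is a lower bound computed against the floor of 3 counts per library. Where they held 1 to 3 counts in total, the ratio is given with its 95% counting interval.

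Gene lists covering 30 pathways and cell types were fixed before the data were examined. Each list was tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 30 lists. Beside it stand the numbers of members called over all genes and adjusted over the list alone, the median log2 fold change, camera with a correlation estimated from the data, and fry, which tests whether a list's genes move on balance in a single direction. List medians came out the same when genes at 0 in a group were set to their bound. Lists share members, such as the 4 genes that the mesenchymal transition and cranial mesenchyme lists have in common.

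The named genes follow a rule fixed before the data were examined. It took Lats1 and Lats2. It took the 10 genes with the largest rise and the 10 with the largest fall in fitted log2 fold change. These were among genes past the threshold, with a mean log2 CPM of at least 1 and both DCKO libraries beyond both Control libraries. Here the rule left out predicted models. It took up to 4 called members of each list by p-value, or the member with the smallest p-value as a value. It took Yap1, Wwtr1, Tgfb1, Tgfb2, Tgfb3, Tgfbr1, Tgfbr2, Wnt1 and E2f1, and the sex-linked Xist, Ddx3y, Eif2s3y, Kdm5d and Uty.

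The test was checked on simulated data with 2 libraries per group and 18641 genes in the fit. It recovered 10% of 100 genes simulated with a 2-fold change and 63% of 100 with a 4-fold change, with 11 false calls and 1 call of the wrong sign. Under DESeq2, 33% and 85% were recovered with 67 false calls, and under limma-voom, 8% and 62% with 14. Most 2-fold changes were thus missed in the simulation. Far more genes were called in the data, which eases the adjusted threshold, so these rates do not carry over to the data.

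Alternatives were scaling by DESeq2 size factors, upper quartiles or library totals, leaving out erythroid and mitochondrial genes (the 37 mitochondrial genes of the table are at 0 in all libraries, so only the erythroid genes matter), no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom with limma 3.58.1 and a robust edgeR fit. Others were limma on log2(TPM + 1) and log2(TPM + 0.1) with a mean TPM of at least 1, or on log2(TPM + 1) unfiltered, a block for replicate number, leaving out each library, and other thresholds. Leaving out X and Y genes, leaving out ribosomal RNA cluster genes on chromosome 17, counting list members under each setting, and leaving out members shared by lists were chosen after seeing the data. Where a single library was left in a group, it was assumed to vary like the other group. Splits of the samples were not counted, since each group has 2 libraries. No deposited numeric column was left unused.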

Results

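The data are RNA sequencing counts from the cranial neural tube of mouse embryos at embryonic day 10.5. Control and DCKO groups held 2 libraries each, from separate embryos. In DCKO embryos, Cre driven by Wnt1 regulatory sequences, which are active in the dorsal neural tube and its neural crest, was used to delete floxed Lats1 and Lats2. These genes encode the Hippo pathway kinases that restrain the coactivators YAP and TAZ. Totals per library ranged from 41798361 to 55137810 counts. The only comparison the design gives is DCKO against Control, and the series title sets its question, namely how Lats1 and Lats2 bear on YAP, TGF-beta and epithelial-mesenchymal transition in the dorsal cranial neuroepithelium.

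In DCKO neural tubes, lists of TGF-beta response, extracellular matrix, actomyosin, surface ectoderm and hypoxia genes rose in camera with a preset correlation. Lists of neural progenitor, neuronal and Notch pathway genes fell in the same test. With an estimated correlation 0 of the 30 lists passed. That version rests on the 2 residual degrees of freedom, so it had little room to pass any list. Of 19207 tested genes, 1716 were higher and 1558 were lower in DCKO, together 17.05%, and 6896 had an unadjusted p under the same threshold. A fold of at least 2 was found for 1454 of the higher and 1068 of the lower genes. Both DCKO libraries lay outside both Control libraries for 66.4% of tested genes, against 33.3% by chance. The number of calls changed with the pair of libraries that set the spread, since leaving out 1 library leaves a single one in its group. When a Control was left out, the DCKO pair (Spearman's rho 0.966) set the spread, and calls were far fewer. When a DCKO library was left out, the closer Control pair (0.983) set it, and calls rose. Such numbers cannot tell dependence on a library from this change of spread. In each of these fits, 0 called genes took the opposite sign, which is no check for genes whose groups do not overlap. Of the 115 named genes that passed the threshold, 75 kept their call without Control 1, 55 without Control 2, 113 without DCKO 1 and 114 without DCKO 2. None of these genes took the opposite sign in any of those fits. All 115 had both DCKO libraries beyond both Control libraries, so a change of sign was hardly possible. Scaled to library totals, 1219 genes were higher and 3744 lower, with the median of all genes moved by -0.35 on the log2 scale.

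**Figure D1:**
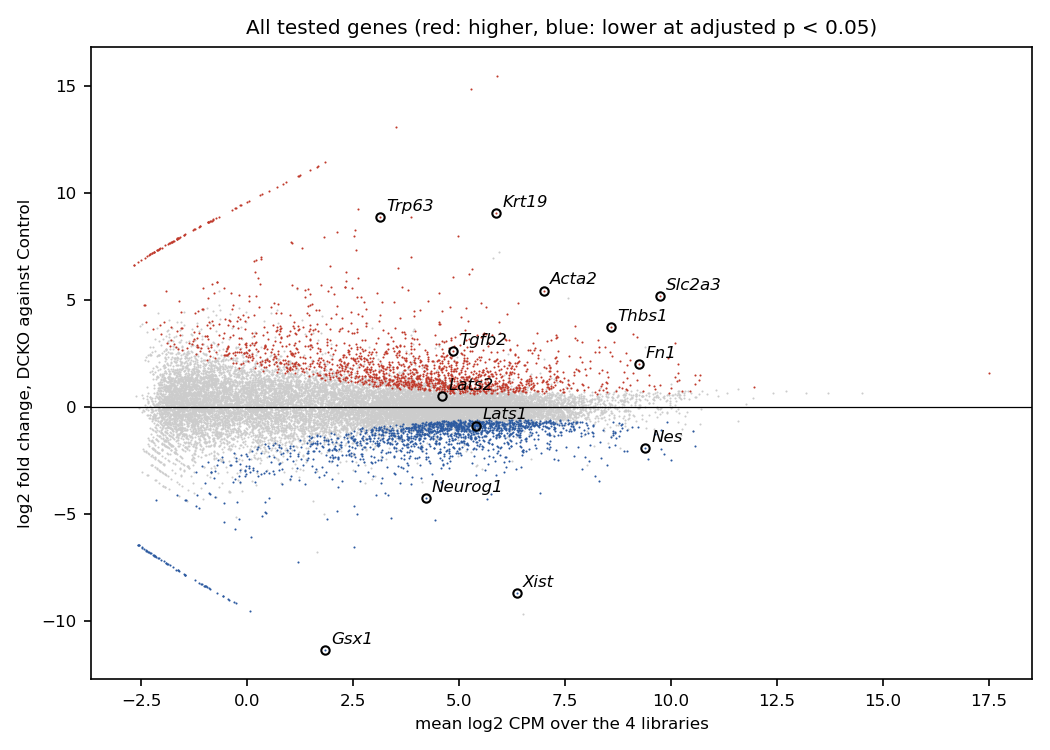
Each point is a tested gene, with its mean log2 CPM over the 4 libraries on the x axis and its log2 fold change, DCKO against Control, on the y axis. Red points are the 1716 higher and blue points the 1558 lower genes, grey points were not called, and the slanted lines of points at the upper and lower left are genes at 0 in both libraries of a group, whose fitted fold is no measurement.

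The groups also differed in ways other than the deleted genes. Both DCKO embryos carried the Cre transgene and both Control embryos lacked it. Effects of the transgene therefore cannot be separated from loss of Lats1 and Lats2. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254 on GRCm38), the long noncoding RNA transcribed from the inactive X chromosome, had 10837 and 7786 counts in Control and 8 and 22 in DCKO, the difference between embryos with and without an inactive X, so embryo sex cannot be separated from group. Ddx3y, Eif2s3y, Kdm5d and Uty on the Y chromosome were listed at 0 in all 4 libraries, as were all 1570 Y-linked genes of the table, so the Y chromosome gives no check. Of X-linked genes known to escape inactivation, chosen after values were seen, Eif2s3x had a log2 fold change of -0.62 (adjusted p 0.0547), Kdm6a -0.69 (0.149), Kdm5c -0.32 (0.193) and Ddx3x -0.02 (0.958), so that 0 of these 4 passed. Of 602 tested X-linked genes, 53 were higher and 38 lower, 15.1% against 17.1% of the other genes, with a median log2 fold change of 0.06. Genes overlapping the ribosomal RNA cluster on chromosome 17 took 13.2% and 12.4% of Control counts and 24.7% and 30.3% of DCKO counts. Erythroid genes took 0.295% and 0.431% in Control and 0.0809% and 0.0592% in DCKO. With X and Y genes left out, 1658 genes were higher and 1506 lower, and without the ribosomal cluster 1720 and 1583. Across genes, which are not independent replicates, Spearman's rho was 0.983 between Control libraries, 0.966 between DCKO libraries and 0.921 to 0.928 between groups.

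Lats1 (ENSMUSG00000040021, chromosome 10, 7681214 to 7716460) had 54.9 ± 15.1 CPM in Control and 29.8 ± 0.253 in DCKO (SD, n = 2), lower in both DCKO libraries. Its log2 fold change of -0.88 (SE 0.23) missed the threshold in edgeR, with an adjusted p of 0.0538, and it passed with library totals (-1.23, a scaling that moved the median of all genes by -0.35), no filter (-0.91) or DESeq2 (-0.93). On TPM filtered at a mean of 1 it also passed, at -0.97 or -1.07 by pseudocount, but on unfiltered log2(TPM + 1) it did not (-0.97, adjusted p 0.130). Without a single library its adjusted p lay between 0.0656 and 0.280. Lats2 (ENSMUSG00000021959, chromosome 14, 57689662 to 57758388), which overlaps the model Gm49361, had 26.7 and 13.3 CPM in Control and 21.2 and 35.3 in DCKO, with overlapping groups, a log2 fold change of 0.50 (SE 0.41) and an adjusted p of 0.426 in edgeR. The log2 fold change of Lats2 was 1.08 and 0.05 without Control 1 and Control 2, and 0.81 and 0.08 without DCKO 1 and DCKO 2. Cre acts in part of the dissected tissue, and the sources do not give the floxed exons. A gene's count can thus hold reads from exons that remain. The counts of Lats2 therefore do not check the genotype. Yap1 had a log2 fold change of -0.24 (SE 0.25, adjusted p 0.520), and without DCKO 1 it was 0.02. Wwtr1, which encodes TAZ, had 0.25 (SE 0.16, adjusted p 0.320), -0.10 with library totals, and 0.15 to 0.31 without a single library.

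**Figure D2:**
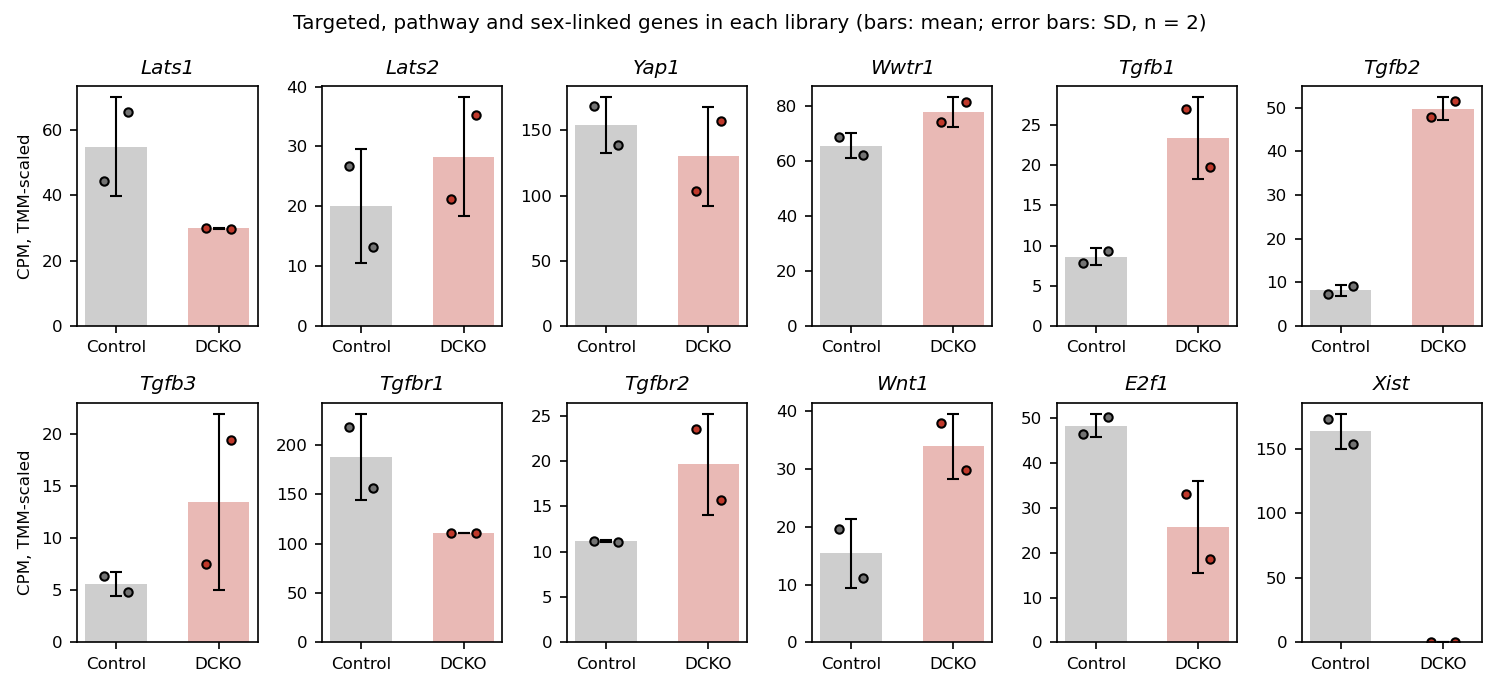
TMM-scaled CPM of the targeted, pathway and sex-linked genes, with a point per library, bars at the group mean and error bars for the SD (n = 2). Tgfb1, Tgfb2 and Xist passed the threshold, Lats1 lay lower in both DCKO libraries without passing it, and the Lats2 points of the groups overlap.

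YAP/TAZ target genes rose in DCKO: 13 of 21 were higher and 1 was lower, with a median log2 fold change of 1.71. Adjusted over the list alone, 16 were higher and 1 lower. In the same libraries, 11 of 15 surface ectoderm, 11 of 16 endothelial, 10 of 22 cranial mesenchyme and 7 of 11 pericyte markers were higher. Of the erythroid markers, 8 of 14 were lower, and 0 of 14 macrophage markers passed. The rise of the YAP/TAZ targets is therefore not separated from cell composition. Tgfb2, which encodes a TGF-beta ligand, rose from 8.18 ± 1.23 to 49.8 ± 2.61 CPM (log2 fold change 2.60, SE 0.19, adjusted p 0.00602). Ankrd1, a widely used YAP target, had 0 counts in Control and 0.650 and 10.6 CPM in DCKO 1 and DCKO 2, so that its bound of at least 105-fold rests mostly on DCKO 2. Myof, a membrane repair protein, rose by a log2 fold change of 2.60 (SE 0.23). Fjx1 fell by 2.00 (SE 0.18). The list's adjusted p in camera was 1.87e-10, and adjusted p = 0.205 with an estimated correlation. Without Control 1, 6 members were higher, and without Control 2, 4. Ankrd1 then had adjusted p-values of 0.132 and 0.129, and without Control 2 Myof had 0.0511 and Fjx1 0.0513.

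Hippo pathway components went both ways, with 3 of 22 higher and 3 lower, and 6 and 4 adjusted over the list alone. Tead1 and Tead3, DNA-binding partners of YAP, rose by log2 fold changes of 1.03 (SE 0.20) and 1.34 (SE 0.19). Taok2, an upstream kinase, fell by 1.23 (SE 0.15) and Mob1b, a LATS cofactor, by 1.26 (SE 0.21). The list had a median of -0.15, which was 0.12 without DCKO 1 and -0.01 without DCKO 2, a mean of 0.13 and a camera adjusted p of 0.989, and camera and fry differed in sign. The rough size of these changes held without either Control, while the passes did not, in fits whose spread comes from the DCKO pair alone. Their direction could hardly change, since the groups did not overlap for these genes. Without Control 1 and Control 2 in turn, log2 fold changes were 1.19 and 0.85 for Tead1, 1.32 and 1.32 for Tead3, -1.24 and -1.26 for Taok2 and -1.04 and -1.49 for Mob1b, while Tead1 had adjusted p-values of 0.115 and 0.198, Tead3 0.120 and 0.122, Taok2 0.0774 and 0.0811, and Mob1b 0.156 and 0.0780. In edgeR 0 members passed without Control 1 and 0 without Control 2, with 8 and 7 at an unadjusted p under the threshold, and without DCKO 1, 5 were higher.

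TGF-beta response genes rose, with 15 of 21 higher, a median log2 fold change of 2.70 and, adjusted over the list alone, 17 higher and 2 lower. Thbs1, a matricellular activator of latent TGF-beta, rose from 53.8 ± 0.111 to 712 ± 231 CPM (log2 fold change 3.73, SE 0.28). Acta2, smooth muscle actin and also a pericyte marker, rose from 5.82 ± 1.52 to 250 ± 118 CPM (5.42, SE 0.45), and the transcriptional repressor Bhlhe40 by a log2 fold change of 4.85 (SE 0.36). The camera adjusted p was 1.30e-17, and adjusted p = 0.114 with an estimated correlation. Markers of cell types that express such genes were higher in the same libraries, with 7 of 11 pericyte and mural, 10 of 22 cranial mesenchyme and 11 of 16 endothelial markers, so the rise is not separated from cell composition. Among pathway components, 5 of 19 were higher, with a median of 0.38 and, adjusted over the list alone, 7 higher and 1 lower. Besides Tgfb2, these included Tgfb1 (1.44, SE 0.24), the coreceptor Tgfbr3 (2.16, SE 0.26) and the pseudoreceptor Bambi (1.22, SE 0.17). The component list had a camera adjusted p of 0.0126, and adjusted p = 0.205 with an estimated correlation. It reached 0.0648 without Control 2, and its median was 0.12 without DCKO 2. Without Control 1, 8 response genes and 2 components were higher, and without Control 2, 5 and 1. Tgfb1 then had adjusted p-values of 0.146 and 0.116 and Bambi 0.104 and 0.131, and without Control 2 Tgfbr3 had 0.0660. Tgfb3 had a log2 fold change of 1.26 (adjusted p 0.126), Tgfbr1 -0.76 (0.0600) and Tgfbr2 0.82 (0.0823). Without DCKO 1 Tgfb3 passed at 0.00598, but without DCKO 2 it had 0.41 (0.331), and Tgfbr2 passed at 0.0120 without DCKO 2 but had 0.49 (0.129) without DCKO 1.

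Genes of mesenchymal transition, matrix and contraction rose alongside. In the list of epithelial-mesenchymal transition and mesenchymal genes, 13 of 19 were higher (16 adjusted over the list alone), with a median log2 fold change of 1.62. Fn1, fibronectin, rose from 247 ± 7.67 to 975 ± 83.9 CPM (1.98, SE 0.16), and the matrix protease Mmp2 rose by 1.95 (SE 0.17). Its camera adjusted p was 8.64e-11, and adjusted p = 0.114 with an estimated correlation. Of 33 extracellular matrix genes, 27 were higher (31 adjusted over the list alone), with a median of 2.21. Hspg2, the basement membrane proteoglycan perlecan, rose from 90.7 ± 1.29 to 538 ± 58.7 CPM, and the neighbouring collagen IV genes Col4a1 and Col4a2, which overlap, by 2.21 and 2.15. This list's camera adjusted p was 8.70e-31, and adjusted p = 0.169 with an estimated correlation. Of 21 actomyosin genes, 18 were higher (21 adjusted over the list alone), with a median of 1.93, among them the myosin light chain Myl9 (2.96, SE 0.18) and calponin Cnn2 (2.78, SE 0.16). Their camera adjusted p was 1.85e-22, and adjusted p = 0.123 with an estimated correlation. In the same libraries, 10 of 22 cranial mesenchyme and 7 of 11 pericyte markers were higher. Without Control 1, 2 transition, 12 matrix and 8 actomyosin genes were higher, and without Control 2, 2, 10 and 4. Without Control 2, Mmp2 had an adjusted p of 0.0520.

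Epithelial genes, which fall in a textbook epithelial-mesenchymal transition, were also higher in DCKO: 13 of 23 junction and polarity genes rose and 2 fell (18 and 3 adjusted over the list alone), with a median of 2.35 that was 1.42 without DCKO 2. Cdh3, P-cadherin, rose from 0.865 ± 0.342 to 57.0 ± 16.2 CPM (6.05, SE 0.40), and the claudins Cldn4 (7.34, SE 0.49) and Cldn7 (5.28, SE 0.48) rose too. Cldn4 had 4 counts in each Control library, so genes such as Cdh3 and Cldn4 had little room to fall. The list shares 3 members, Cdh1, Epcam and Esrp1, with the surface ectoderm markers. Its rise is not separated from more surface ectoderm and does not show whether the neuroepithelium kept its epithelial character. The camera adjusted p was 3.70e-12, and adjusted p = 0.114 with an estimated correlation. Markers of surface ectoderm and placodes rose, with 11 of 15 higher (14 adjusted over the list alone), a median of 3.45, a camera adjusted p of 1.86e-22, and adjusted p = 0.114 with an estimated correlation. Trp63, the transcription factor of stratified epithelia, rose from 0.0357 ± 0.00536 to 17.5 ± 0.0651 CPM, and Wnt6 from 0.224 ± 0.0462 to 29.0 ± 1.56. Trp63 had 2 counts in each Control library, under the floor of 3 counts, so the size of its rise is uncertain. The keratins Krt8 and Krt18 rose by log2 fold changes of 4.03 (SE 0.29) and 4.63 (SE 0.30). Without Control 1, 7 junction and 7 ectoderm genes were higher, and without Control 2, 4 and 5.

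The named genes with the largest fitted rises included keratins and other proteins of epithelia. Genes at 0 in Control have no measured fold, so their place among these is uncertain. With 0 counts in both Control libraries, Gabrp was at least 134-fold higher, Cdcp1 119-fold, Gfra3 117-fold, Ap1m2 88.5-fold, Anxa8 86.4-fold and Trim29 86.3-fold, each a lower bound. Krt19 rose from 0.217 ± 0.0549 to 117 ± 80.0 CPM (9.05, SE 0.72), and Krt7, which overlaps Gm671 and had 7 and 0 counts in Control, by 8.85 (SE 0.73). Gfra3, a receptor of neurons and glia, had 1.95 and 10.6 CPM in DCKO 1 and DCKO 2, so that its bound rests mostly on DCKO 2, and it did not pass without Control 1 (adjusted p 0.0680) or Control 2 (0.0715). The other genes of this paragraph passed in edgeR without any single library.

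Neural genes fell in the same libraries. Of 20 neural progenitor genes, 12 were lower (14 lower and 1 higher adjusted over the list alone), with a median of -1.19. The progenitor filament Nes went from 1066 ± 109 CPM in Control to 280 ± 39.2 in DCKO, the transcription factor Sox3 from 142 ± 3.84 to 18.9 ± 3.46, and Olig3 from 20.4 ± 4.81 to 0.562 ± 0.123. The camera adjusted p was 9.32e-11, and adjusted p = 0.114 with an estimated correlation. Of 27 neuronal differentiation genes, 12 were lower (18 adjusted over the list alone), with a median of -1.36. The proneural genes Neurog1 (-4.27, SE 0.37) and Neurod4 (-4.03, SE 0.36) fell. The camera adjusted p was 5.59e-12, adjusted p = 0.205 with an estimated correlation, and fry gave 0.0552. Medians of other cell types were 3.45 for surface ectoderm, 2.14 for pericyte, 1.73 for endothelial and 1.62 for cranial mesenchyme markers, but -2.02 for erythroid markers. The fall of neural genes is therefore not separated from a lower share of neural cells. Without Control 1, 5 progenitor and 5 neuronal genes were lower, without Control 2, 6 and 3, and without DCKO 1, 13 and 23.

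Among the largest falls, Gsx1, a homeobox gene of dorsal progenitors, had 0 counts in DCKO and was at least 89.8-fold lower. Msx3, a dorsal neural tube homeobox gene, went from 41.9 ± 2.59 to 1.06 ± 1.08 CPM, Dbx1, of intermediate progenitors, from 103 ± 15.3 to 6.05 ± 2.93, and the neuropeptide receptor gene Adcyap1r1 from 96.5 ± 5.13 to 4.89 ± 1.60. Log2 fold changes were -5.00 (SE 0.75) for Lhx1, -4.64 (SE 0.70) for Otp and -4.10 (SE 0.45) for Rhbdl3. Msx3 had adjusted p-values of 0.0517 without Control 1 and 0.0528 without Control 2, where Lhx1 had 0.0731 and Otp 0.0610.

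Notch pathway genes fell on balance, with 7 of 16 lower and 2 higher (8 and 2 adjusted over the list alone) and a median of -0.52. Dll1, a Notch ligand, went from 86.1 ± 0.273 to 11.0 ± 3.15 CPM (-2.96, SE 0.25), and the Notch feedback gene Nrarp fell by 2.88 (SE 0.24). The camera adjusted p was 0.00133, and adjusted p = 0.169 with an estimated correlation. With limma-voom it was 0.0698 and with log2(TPM + 0.1) 0.0961. The Notch list shares 4 members, Hes1, Hes5, Lfng and Notch1, with the neural progenitor list. Its fall is not separated from a lower share of neural cells. Of 28 cell cycle genes, 7 were lower (8 adjusted over the list alone), with a median of -0.48, a camera adjusted p of 9.24e-06, adjusted p = 0.301 with an estimated correlation, and 0.0524 by fry. E2f2, a transcription factor of S phase entry, went from 31.2 ± 0.517 to 3.12 ± 1.04 CPM, and cyclin E, Ccne1, from 58.2 ± 5.36 to 14.7 ± 3.60. These falls are not separated from effects of the Cre transgene, which only DCKO embryos carried. Without Control 1, and likewise without Control 2, 3 Notch genes and 1 cell cycle gene were lower, and without DCKO 1, 13 cell cycle genes. Ccne1 had adjusted p-values of 0.0556 without Control 1 and 0.0513 without Control 2. The log2 fold change of E2f1, named in the Cre allele, was -0.91 (SE 0.29, adjusted p 0.0891), and it passed at 0.00624 without DCKO 1 but had -0.55 (0.0739) without DCKO 2.

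Neural crest genes as a list did not pass, with 4 of 20 higher and 2 lower (6 and 3 adjusted over the list alone), a median of 0.17 and a camera adjusted p of 0.378. The median was 0.07 without Control 1, 0.38 without Control 2, 0.45 without DCKO 1 and -0.02 without DCKO 2. Snai2 (2.28, SE 0.30), Tfap2a (2.35, SE 0.31) and Erbb3 (4.88, SE 0.75) were higher and Pax7 (-1.86, SE 0.20) was lower. Without DCKO 1 the list passed upward, at 0.00335 with 8 members higher and 4 lower, and without Control 1 and Control 2 in turn, 0 passed in edgeR, with 7 and 10 at an unadjusted p under the threshold. There, Snai2 had adjusted p-values of 0.0915 and 0.0803, Tfap2a 0.0785 and 0.0621, Erbb3 0.0823 and 0.0773, and Pax7 0.0624 and 0.0504. The DCKO libraries also differed from each other: Erbb3 had 8.80 and 33.8 CPM in DCKO 1 and DCKO 2.

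Regional lists did not pass either. Of 24 dorsal neural tube and roof plate genes, 4 were higher and 2 lower (6 and 3 adjusted over the list alone), with a camera adjusted p of 0.283. The dorsal BMP ligands Bmp6 (2.29, SE 0.16), Bmp7 (1.92, SE 0.16) and Bmp4 (2.61, SE 0.23) rose, Bmp6 in a locus that overlaps Txndc5. Of 17 ventral genes, 1 was higher and 2 lower (1 and 3 adjusted over the list alone), with 0.283. Of 21 midbrain-hindbrain genes, 1 was higher and 4 lower (the same numbers adjusted over the list alone), with 0.129 in camera and 0.0485 in fry. Pax2 had -3.59 (SE 0.49), Irx2 -1.49 (SE 0.22) and Otx2, a forebrain and midbrain gene, 1.00 (SE 0.16). Without Control 2, Bmp7 had 0.0527, Bmp4 0.0514, Pax2 0.0715, Irx2 0.0619 and Otx2 0.134, and without Control 1 the last 3 had 0.0702, 0.0924 and 0.142. Called members were 3 dorsal genes higher and 1 lower, 1 ventral and 1 midbrain-hindbrain gene lower without Control 1, and 1 dorsal gene higher without Control 2, where 0 ventral and 0 midbrain-hindbrain genes passed in edgeR and 5 and 10 had an unadjusted p under the threshold. Without DCKO 1, 5 dorsal genes were lower, and without DCKO 2, 4 ventral genes were lower and 3 higher and 3 midbrain-hindbrain genes higher.

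Wnt and BMP response genes did not pass as lists. Of 15 Wnt response genes, 1 was higher and 2 lower (1 and 4 adjusted over the list alone), with a camera adjusted p of 0.129, and Fzd10 went from 146 ± 0.539 to 34.7 ± 8.58 CPM. The Wnt list passed downward without Control 2 (0.0385) and without DCKO 1 (0.00148, with 6 members lower), and 1 member was lower without each Control. Wnt1 itself had 1.14 (SE 0.31, adjusted p 0.0601), and it passed without DCKO 2 at 0.0361. Of 15 BMP response genes, 1 was higher and 3 lower (6 and 3 adjusted over the list alone), with 0.872. Id2 and Id3, inhibitors of basic helix-loop-helix factors, fell by log2 fold changes of 0.90 (SE 0.18) and 1.33 (SE 0.26). Without Control 1 and Control 2 in turn, 0 BMP response genes passed in edgeR, 5 and 7 had an unadjusted p under the threshold, and adjusted p-values were 0.179 and 0.149 for Id2 and 0.127 and 0.105 for Id3. Without DCKO 1, 5 were higher.

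All 21 hypoxia and glycolysis genes rose in DCKO, with a median log2 fold change of 2.66. Slc2a3, a glucose transporter, rose from 46.7 ± 4.93 to 1668 ± 168 CPM (5.16, SE 0.21, adjusted p 0.00280). Adm, the vasodilator peptide adrenomedullin, rose from 1.01 ± 0.0770 to 74.8 ± 6.44 CPM, and Ndrg1, a stress-responsive gene, from 3.84 ± 0.0147 to 96.4 ± 3.04. The camera adjusted p was 2.92e-43, and adjusted p = 0.114 with an estimated correlation. Without Control 1, 13 members were higher and without Control 2, 10. Of 18 p53 response genes, 10 were higher and 1 lower (11 and 2 adjusted over the list alone), with a median of 1.48, a camera adjusted p of 7.67e-07, and adjusted p = 0.205 with an estimated correlation. Perp, a desmosomal protein as well as a p53 target, had 6.46 (SE 0.29), Plk2 2.23 (SE 0.16) and Btg2, an antiproliferative gene, -2.31 (SE 0.20). Immediate early and heat shock genes had 8 of 16 higher and 1 lower (11 and 1 adjusted over the list alone), with a median of 2.61, a camera adjusted p of 9.69e-08, and adjusted p = 0.114 with an estimated correlation. Fos had 6.02 (SE 0.51), and the near-identical Hspa1a and Hspa1b, whose reads cannot be assigned with certainty, 7.98 and 6.45. Without Control 1, 5 p53 and 4 immediate early or heat shock genes were higher, and without Control 2, 2 and 5.

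Markers of other cell types moved in different directions. Of 14 erythroid markers, 8 were lower (9 adjusted over the list alone), with a median of -2.02, a camera adjusted p of 7.05e-09, and adjusted p = 0.205 with an estimated correlation. The erythrocyte anion exchanger Slc4a1 went from 45.4 ± 10.1 to 8.72 ± 0.815 CPM and the embryonic globin Hbb-bh1, whose reads can be shared with other globin genes, from 766 ± 219 to 181 ± 6.63. Of 16 endothelial markers, 11 were higher (14 adjusted over the list alone), with a median of 1.73, a camera adjusted p of 4.98e-09, adjusted p = 0.205 with an estimated correlation, and 0.0529 by fry. The VEGF receptors Flt1 and Kdr rose by 3.13 (SE 0.34) and 2.04 (SE 0.31). Without Control 1 and Control 2, 6 and 2 erythroid markers were lower, and 1 and 0 endothelial markers were higher, with 13 and 12 at an unadjusted p under the threshold. Kdr had adjusted p-values of 0.0774 and 0.0964 then, and Flt1 0.0539 without Control 2. Of 14 macrophage markers 0 passed in edgeR, 1 had an unadjusted p under the threshold, and DESeq2 called 1. Their camera adjusted p was 0.412, and without DCKO 2 it was 8.66e-04 with 7 higher. Mrc1 had 4.58 and 8.14 CPM in Control and 27.3 and 10.4 in DCKO, and it passed without DCKO 2 (0.00983).

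Mesenchymal and muscle markers were higher in part. Of 22 cranial mesenchyme markers, 10 were higher (15 adjusted over the list alone), with a median of 1.62, a camera adjusted p of 5.65e-08, and adjusted p = 0.135 with an estimated correlation. Pdgfrb, a receptor of mesenchyme and pericytes, rose from 31.5 ± 1.81 to 139 ± 23.2 CPM and Foxc1 from 21.4 ± 1.35 to 63.6 ± 11.5. Of 11 pericyte and mural cell markers, 7 were higher and 1 lower (9 and 1 adjusted over the list alone), with 1.81e-07 in camera, and adjusted p = 0.114 with an estimated correlation. Of 12 muscle markers, 3 were higher (4 adjusted over the list alone), with 0.00806, and adjusted p = 0.205 with an estimated correlation. The 3 were Acta1, Actc1 and Des, and Des is also on the pericyte list. Myod1, Myog, Mymk, Tnni1 and Myl1 of the list's 17 members were not tested, with at most 13 counts in any library. Acta1 had 2 counts in Control and a ratio of 239 (95% interval 65.7 to 1982). Of 12 chondrogenic genes, 4 were higher (6 adjusted over the list alone), with 1.96e-04, and adjusted p = 0.152 with an estimated correlation. Hapln1, a cartilage link protein, rose from 24.3 ± 6.27 to 189 ± 49.8 CPM. Of 16 Schwann cell precursor and cranial ganglion markers, 2 were higher and 1 lower (5 and 2 adjusted over the list alone), with 0.611. Without DCKO 1 they were 7 and 6, and without Control 1 and Control 2 in turn, 0 passed in edgeR, with 7 and 6 at an unadjusted p under the threshold. Without Control 1, 1 mesenchyme, 3 pericyte, 1 muscle and 2 chondrogenic genes were higher, and without Control 2, 2 mesenchyme, 1 pericyte, 0 muscle and 1 chondrogenic gene, with 5 muscle markers at an unadjusted p under the threshold. Without DCKO 2, 7 chondrogenic genes were higher. Pdgfrb had 0.0513 without Control 2, Foxc1 0.0702 and 0.0872 without Control 1 and Control 2, and Acta1 0.0569 and 0.0504.

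**Figure D3:**
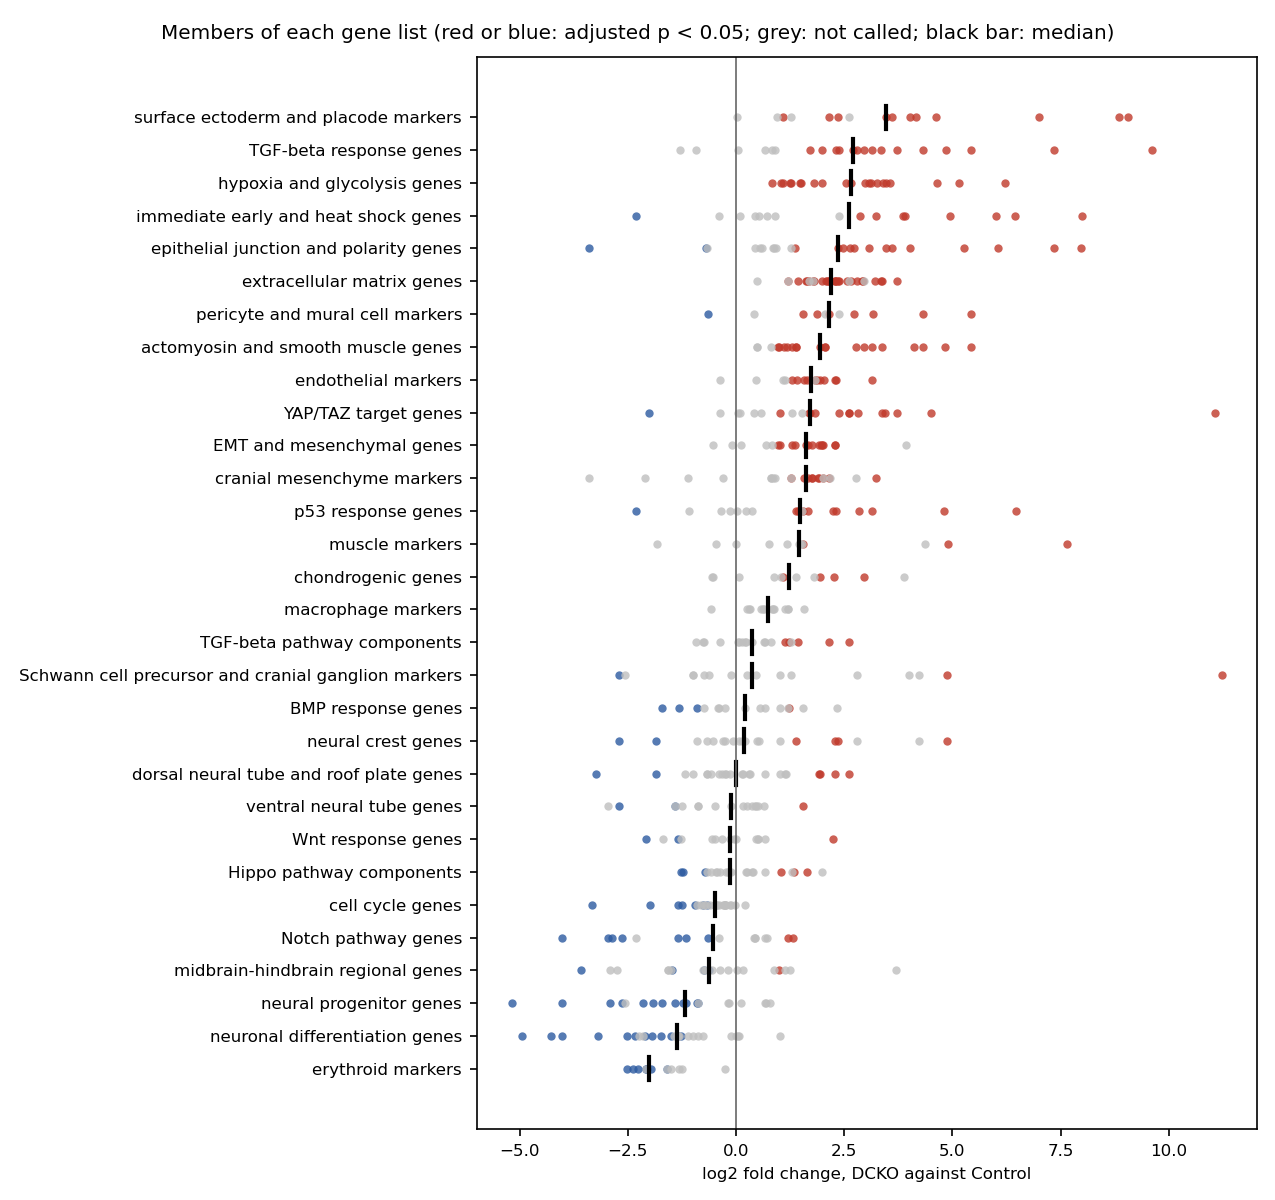
Each point is a tested member of a gene list, placed by its log2 fold change, DCKO against Control, on the x axis, with the 30 lists on the y axis ordered by median (black bar). Red and blue points passed the threshold upward and downward and grey points did not; surface ectoderm markers have the highest median (3.45) and erythroid markers the lowest (-2.02).

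With the preset correlation, 21 of the 30 lists passed in camera, 16 upward and 5 downward. In camera 0 passed with an estimated correlation, where the smallest adjusted p was 0.114, and 19 passed by fry. The version with an estimated correlation rests on the 2 residual degrees of freedom. The mesenchymal transition list had an estimated correlation of -0.0104, below the preset 0.01, and its camera adjusted p still went from 8.64e-11 to 0.114. For that list, the failure therefore does not show that correlation between genes accounts for the result. Estimated correlations differed between lists, from -0.0634 for pericyte to 0.858 for macrophage markers. Where they lay well above the preset, as at 0.439 for extracellular matrix and 0.296 for YAP/TAZ targets, the preset p-values may be too small. These estimates rest on the same 2 residual degrees of freedom. The authors' table has 1962 genes higher and 1660 lower at the same threshold on its false discovery rate. Of these, 1377 were also higher and 1306 also lower in the edgeR test here, with 0 called in opposite directions. Among genes called here, 106 were in the authors' table without passing and 485 were not in it, and 939 genes passed in the authors' table alone. The log2 fold changes come from the same counts and had a Pearson r of 0.999997 across genes. In the authors' table Lats1 has a false discovery rate of 0.0207 and Lats2 of 0.271.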

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

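Leaving out X and Y genes, ribosomal RNA cluster genes or shared list members, and counting list members under each setting, were chosen after seeing the data. Against 1716 higher and 1558 lower genes, the count-based settings not named below stayed within 1.5 times, and no called gene took the opposite sign in a count-based setting, while 1 did in each TPM setting. Library totals gave 3744 lower genes and DESeq2 2672. Filtered log2(TPM + 1) and log2(TPM + 0.1) gave 1007 and 958 higher, with the median of all genes moved by -0.21 and -0.23. Unfiltered log2(TPM + 1) gave 0 higher and 0 lower, with 6446 genes at an unadjusted p under 0.05. A replicate block gave 1002 and 776, but same-numbered libraries shared no deviation (correlation across genes -0.04), which gives no sign of pairing. That value cannot exclude littermates or joint processing, which the labels do not give. An adjusted p under 0.10 gave 2900 and 2704, by its construction. Leaving out a library gave 155 to 2619 higher and 72 to 2565 lower genes. Lats1 passed with library totals (-1.23, where the median of all genes moved by -0.35), no filter (-0.91), DESeq2 (-0.93), filtered log2(TPM + 1) (-0.97) and filtered log2(TPM + 0.1) (-1.07), against -0.88, but not on unfiltered log2(TPM + 1) (adjusted p 0.130), and its adjusted p over all alternatives with a test is lowest in DESeq2 at 0.00443. With an estimated correlation, camera gave 0.205 for the YAP/TAZ and TGF-beta component lists and 0.114 for the TGF-beta response, mesenchymal transition and epithelial lists, and these 5 kept their direction in every setting. Without a library, the component list ranged from 0.00683 to 0.0648 and the neural crest list from 0.00335 to 0.704. Some results short of the threshold changed sign: Yap1 ranged from -0.58 to 0.0202 without a library, and Wwtr1 was -0.10 with library totals, by the same shift. The Hippo list changed to up with upper quartiles (0.954), a mean CPM of at least 1 (0.891), log2(TPM + 1) (0.943), log2(TPM + 0.1) (0.941), fry (0.858), and without Control 1 or DCKO 1, and ranged from 0.327 to 0.759 without a library. Without a library the BMP response list ranged from 0.213 to 0.918 and the macrophage list from 8.66e-04 to 0.587, with changes of sign. Where no construction is named, the cause was not tested. DESeq2 was not run on lists. In the simulation 10% of 2-fold changes were recovered, but far fewer genes changed there than were called here. Of the calls here, 1454 of 1716 higher and 1068 of 1558 lower genes had a fold of at least 2, so smaller changes were called too. The simulated rate therefore does not carry over to these data.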

Other observations

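Genes in the next paragraphs lie outside the rule for named genes and were chosen after their values were seen. Replication histone genes, whose messages mostly lack a poly(A) tail and which have near-identical copies, were lower in DCKO: 30 of 68 tested genes passed the threshold downward, with a median log2 fold change of -1.37 that stayed negative in every setting run, scalings included. The labels describe polyadenylated RNA, yet Rn7sk, Rmrp and Rpph1, which lack such tails, took 1.53% to 3.02% of each library's counts, so the kind of library is uncertain, and with it whether the histone values measure expression. In other classes that mostly lack such tails most members did not pass: 1 of 27 snRNA genes was higher and 2 lower (median log2 fold change -1.08), 10 and 7 of 126 snoRNA genes (0.50), 4 and 4 of 36 miscellaneous RNA genes (0.83), 0 and 0 of 4 ribozymes (0.90) and 5 and 0 of 13 scaRNA genes (1.25). Histone genes took 3.95% and 5.49% of Control counts and 1.39% and 1.74% of DCKO counts. Against 30, 53 histone genes were lower with library totals, 51 in DESeq2 and 55 on filtered log2(TPM + 1), and 0 on unfiltered log2(TPM + 1). Their median was -1.69 without Control 1, -1.17 without Control 2, -1.35 without DCKO 1 and -1.59 without DCKO 2. The imprinted RNA H19 had 113 ± 11.8 CPM in Control and 1069 ± 78.2 in DCKO (n = 2), and its neighbour Igf2, a growth factor that overlaps Gm49394, had 96.2 ± 5.14 and 1012 ± 710. The nuclear RNA Malat1 had 571 ± 50.3 and 1715 ± 141 CPM, and Neat1 0.660 ± 0.263 and 12.5 ± 0.591.

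Libraries of a group also differed from each other. Control 2 had more of several forebrain genes than Control 1, with 21.8 against 2.11 CPM for Emx2 and 44.3 against 9.09 for Lhx2. DCKO 2 had more of the neural crest and glial genes Sox10 (24.1 against 1.37 CPM) and Foxd3 (12.3 against 0.725) than DCKO 1, and DCKO 1 more of the macrophage receptor Csf1r (32.5 against 8.34).

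All tests below except the second ectoderm list were chosen after the result was seen, and the labels record neither embryo sex nor differences in dissection, so both stay open for every pattern. Surface ectoderm and epithelial genes were higher in DCKO, and the genotype, the biological difference in the design, remains an untested explanation. Argued against is a lower share of neural cells that raises every other cell type alike, since of 5 lists the erythroid markers had a median of -2.02 (median absolute deviation 0.391), but the other medians were positive, at 3.45 for surface ectoderm, 1.73 for endothelium, 1.62 for cranial mesenchyme and 0.74 for macrophages (-0.49 without DCKO 1), so a lower neural share with unequal rises is not excluded. More surface ectoderm among the DCKO material may be a source: Krt8 and Krt18 reached 69.7 and 69.0 CPM, and of a second list of ectoderm genes 16 of 18 had a positive log2 fold change, and 5 of the 18 were at or above 1 CPM in Control on average. In that list 8 of 18 (44.4%) were called higher, under the 50% set beforehand as arguing against it. The exact 95% interval of 21.5% to 69.2% holds 50%, but this spread was added to the rule after the value was seen. It also treats the genes as independent, though they come from the same libraries, so it measures no spread between embryos. With 16 of the 18 positive, more surface ectoderm cannot be told apart from other sources.

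Hypoxia and glycolysis genes rose in DCKO. Argued against as the whole cause are scaling and the ribosomal RNA share, though by arithmetic rather than by a separate test. A change of scaling moves all genes by about the same amount, with a median of -0.35 for library totals. The list's median over library totals, upper quartiles, DESeq2 size factors and removal of the ribosomal cluster was at least 2.31, with a median absolute deviation of 0.907 among its members. Stress of the tissue during dissection or storage may contribute: 3 of 8 genes induced by handling were called higher (Fos, Egr1 and Atf3), with log2 fold changes of the 8 from -0.40 to 6.02. Fosb (2.37, adjusted p 0.0634 in edgeR), Junb (0.90, 0.0566) and Jun (0.72, 0.0550) were higher just short of the threshold. Dusp1 had 0.44 (0.375) and Ier2 -0.40 (0.171). Handling was not recorded and runs with the groups, so it cannot be told apart from a response of the tissue itself to the genotype, which was not tested.

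Some genes were on in a single group: 19 called genes had at most 10 counts in each library of a group and at least 200 in each library of the other, bounds set after such genes were seen, with 15 higher in DCKO and 4 lower. Reads assigned to a different one of overlapping genes may be a source for some of them. Overlap with the exons of another gene in GENCODE M21 showed no detectable excess, at 42.1% against 37.3% of other tested genes (odds ratio 1.22, Fisher's exact test p = 0.644). The 11 genes without such overlap have no partner there. The annotation used for counting is not stated, however, and near-identical copies elsewhere were not examined, so misassigned reads stay open for them too. At the 8 overlapping loci the summed counts differed by a median absolute log2 ratio of 2.52 (median absolute deviation 1.81), with 3 loci under 1 (Gm20605, Gm9725 and Prss8). At the loci of Krt7 and Gm20481 the sums were 0.0639 and 0.241 CPM in Control against 29.3 and 85.3 in DCKO, which left next to no Control reads of the overlapped gene to shift. At the other overlapping loci such a shift stays open, since a sum that changes does not exclude it, and a difference due to genotype was not tested.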
